A study of Homo sapiens with 12 samples.

How the data were processed

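RNA was measured in human epidermal equivalents, sheets of stratified epidermis grown from cultured primary keratinocytes at an air-liquid interface. The keratinocytes were grown on contracted collagen (CC) or on acellular dermis (ACD), per the labels. The 12 libraries fell into 5 groups by scaffold and day: ACD day 3 (n = 3), ACD day 7 (n = 3), CC day 3 (n = 2), CC day 7 (n = 2) and CC day 14 (n = 2). Per the labels' protocols, days were counted from seeding on ACD, but on CC from the lift to the air-liquid interface that followed 2 days of submerged culture. CC day 3 and day 7 thus lay 5 and 9 days from the start of submerged culture. Whether ACD cultures also had a submerged phase, and when the cells were seeded on CC, is not given in the sources used here. RNA came from graft pieces of 30 mg, mRNA was purified with oligo-dT beads, and libraries were made strand-specific with dUTP, per the labels' protocols.

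The deposited table holds whole-number read counts per gene that the authors made from their reads, with no normalization, for 62757 genes. CASAVA 1.8.2, bcl2fastq 2.20.0 and build hg38 appear in the submitters' processing notes. The aligner, the counting tool, its strand setting and the annotation are not given in the sources used here. Because the strand setting is not stated, antisense and overlapping genes may share reads, as may paralogs and readthrough genes. Gene symbols and identifiers came from the table. Positions came from GENCODE 29 on the same build, which matched 92.9% of the identifiers. XIST, TSIX and Y-linked genes, 572 in all, were left out of every step, and 29842 genes had no count in any library.

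Counts were analysed with edgeR 4.0.16 in R 4.3.3. After filterByExpr by group, 18632 genes were tested with TMM scaling, a robust quasi-likelihood fit to all 12 libraries with 1 coefficient per group (7 residual degrees of freedom), and Benjamini-Hochberg adjustment over all tested genes at 0.05. Pooling the groups in 1 fit assumes that they share their spread. Log2 fold changes are given with their standard error. Where a list had members without a count in a group, its median was also computed with that group at a floor of 3 counts over the group, which is given where it moved a median printed here. CPM values are TMM-scaled and given as mean ± SD over the libraries of a group. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 3 tested members. Each test was repeated with an estimated correlation. Under it no list passed in 7 of the 8 contrasts, and 1 passed in the contrast between the day changes on the 2 scaffolds.

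The groups, the contrasts, 22 pathway lists, 6 cell-type lists and the alternatives were chosen before the data were examined, as was the rule for named genes. That rule took, per contrast, up to 6 genes per direction with the largest change among called genes that had a mean of at least 10 CPM in the higher group, at least 10 counts in the lower group and no overlap between groups, and the largest changes are given among genes that met it. Clones, pseudogenes, small RNAs, readthrough genes and genes with common donor-dependent expression were left out of these. For the contrast between the day changes, overlap was not considered, the mean CPM was over all 10 day 3 and day 7 libraries, and the count minimum applied to each group. The rule also took the 3 members of each list with the smallest p and 10 core genes (KRT5, KRT14, KRT1, KRT10, IVL, LORICRIN, FLG, TGM1, MKI67 and COL1A1). Some genes that met the rule are not reported here. The alternatives were RLE scaling, library size alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter, a filter at 1 CPM, fits to the compared groups alone, a non-robust fit, a threshold of 0.01, glmTreat at a fold of 1.5, a replicate block by graft number, and each library left out in turn. Fits with a library left out were run in edgeR alone, and where 1 library of a group then remains it is assumed to vary like the other groups. Thinning of all libraries to the smallest total, principal components of protein-coding genes without readthrough genes, and lists of nuclear-retained transcripts, glucocorticoid targets and aryl hydrocarbon receptor targets, were added after the data had been seen. The nuclear-retained list holds MALAT1, NEAT1, KCNQ1OT1 and protein-coding genes, and counts per gene of the latter do not tell nuclear from exported mRNA.

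The fit was tested on simulated counts drawn from the real means, dispersions and library sizes with 200 changed genes. Each gene had 1 mean over all 12 libraries and 1 dispersion for all groups, so unequal spread between groups was not simulated. The adjustment is stricter with so few changed genes than in most contrasts of the data, so the recovery below need not hold for the data. For CC against ACD at day 3, run on 18002 genes, it recovered 39 of 63 genes changed by a fold of 4, 19 of 65 at a fold of 2 and 2 of 65 at a fold of 1.5, with 3 false calls among 63. For the contrast between the day changes on the 2 scaffolds, run on 17940 genes, it recovered 27 of 64 at a fold of 4 and 0 of 66 at a fold of 2. Total counts ranged from 30768637 to 41366521 in the ACD libraries and from 56011699 to 77220436 in the CC libraries other than CC day 7 graft 4, which held 245069759. Depth therefore went with the scaffold, and low-count genes were measured with less counting error on CC. The titles name separate grafts, but donors and batches are not given, so p-values measure the spread between these grafts.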

Results

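Gene expression was compared in keratinocytes stratifying on contracted collagen (CC) and on acellular dermis (ACD), at days 3 and 7 on both scaffolds and at day 14 on CC. Total counts per library lay between 30768637 and 245069759, with every CC total above every ACD total. Along the first principal component of the 500 most variable genes, which carried 52.0% of the variance, all day 3 libraries lay below all later ones. The second, with 18.1%, separated the scaffolds. Among the 12 genes with the largest weights at its CC end were the noncoding RNAs RN7SL1, RN7SL2 and RN7SL3 and the readthrough genes SENP3-EIF4A1, FAM47E-STBD1 and RPL17-C18orf32. In a set chosen after the data had been seen, protein-coding genes without readthrough genes, it carried 20.8% and still separated the scaffolds, with the lowest ACD library at 12.7 and the highest CC library at -9.59. The ACD day 7 graft 4 library stood apart from its group, at -2.85 on the first component against 40.8 and 43.1 for grafts 5 and 6. The SD of its log2 ratios to those grafts was 0.588 and 0.720, against 0.276 between grafts 5 and 6. Mitochondrial transcripts took 3.90 ± 0.596% of counts (SD, n = 3) in ACD day 3, 8.27 ± 0.874% (SD, n = 3) in ACD day 7, and between 4.07% and 5.36% in the CC libraries.

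**Figure D1:**
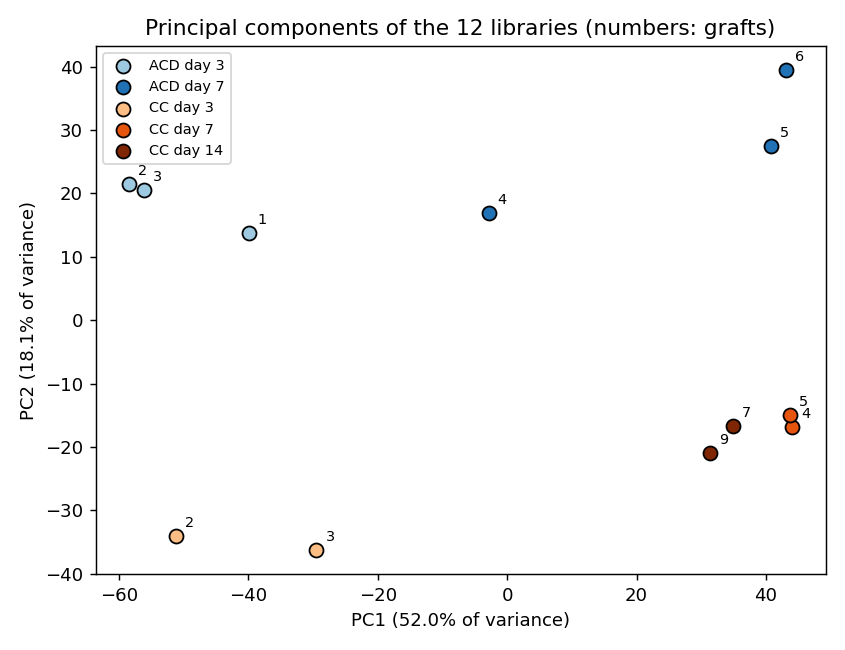
Principal components of the 12 libraries (PC1 horizontal, PC2 vertical, each with its percent of variance), coloured by group and numbered by graft. PC1 separates day 3 from the later days, PC2 the scaffolds, and ACD day 7 graft 4 lies between the ACD day 3 and other ACD day 7 libraries.

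At day 3, interferon-response genes were higher on CC than on ACD. Lists of antioxidant genes, of amino acid synthesis and endoplasmic reticulum stress genes, and of hypoxia and glycolysis genes were lower. Of 25 interferon-response genes, 19 rose and 0 fell (23 rose adjusted over the list alone), with a median log2 fold change of 1.43, among them XAF1 (2.63 ± 0.34), the RNA sensor RIGI (1.55 ± 0.21) and OAS1 (1.11 ± 0.15). The list passed at adjusted p = 2.99e-19, and had adjusted p = 0.110 with an estimated correlation. Of 14 targets of the antioxidant regulator NRF2, 11 fell (12 adjusted over the list alone), including AKR1C1 (-3.39 ± 0.28), whose paralogs may share its reads, NQO1 (-2.38 ± 0.21) and AKR1B10 (-1.94 ± 0.19). Camera gave adjusted p = 4.06e-14, and adjusted p = 0.103 with an estimated correlation. Genes of amino acid synthesis and endoplasmic reticulum stress fell in 9 of 15 cases (11 adjusted over the list alone), among them the serine synthesis enzymes PHGDH (-1.49 ± 0.17) and PSAT1 (-1.97 ± 0.27) and the asparagine synthetase ASNS (-2.07 ± 0.33). As a list, these genes had adjusted p = 2.09e-06, and adjusted p = 0.103 with an estimated correlation. Of 17 hypoxia and glycolysis genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with ADM at -2.45 ± 0.20, the glucose transporter SLC2A1 at -1.31 ± 0.18 and BNIP3 at -1.79 ± 0.29. That list had adjusted p = 0.000345, and adjusted p = 0.261 with an estimated correlation. Without CC graft 2 and without CC graft 3, 6 and 6 NRF2 targets, 3 and 3 amino acid and stress genes, and 3 and 3 hypoxia and glycolysis genes fell. The last of these was 4, 4 and 5 without ACD graft 1, 2 and 3.

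Mucosal and simple-epithelial keratins and retinoid-response genes were also higher on CC at day 3. The mucosal keratins KRT4 (5.16 ± 1.03, adjusted p = 0.00955) and KRT13 (3.97 ± 1.16) and the simple-epithelial keratin KRT19 (3.82 ± 0.89) rose, 3 of 8 genes of that list (4 adjusted over the list alone). KRT4 measured 1157 ± 18.4 CPM (SD, n = 2) in CC day 3 against 32.5 ± 2.92 CPM (SD, n = 3) in ACD day 3. Its list passed at adjusted p = 0.0164, and had adjusted p = 0.330 with an estimated correlation. The largest increases were those of the membrane protein gene MAL (ENSG00000172005.11, chromosome 2, 95025677 to 95053996; 6.75 ± 1.32, adjusted p = 0.00879), MYH15 (5.31 ± 0.65), LRAT, which esterifies retinol (5.09 ± 0.60), ROBO4 (4.93 ± 0.91) and PSCA (4.75 ± 0.93). The largest decreases were those of the matrix metalloprotease gene MMP3 (ENSG00000149968.12, chromosome 11, 102835801 to 102843803; -8.68 ± 1.43, adjusted p = 0.00411), the transcription factor gene ZBTB16 (ENSG00000109906.15, chromosome 11, 114059593 to 114250676; -7.42 ± 0.50, adjusted p = 9.43e-05), the aldehyde dehydrogenase gene ALDH3A1 (-6.72 ± 0.98), UGT1A7 (-5.89 ± 0.88), which shares exons with its neighbours, the noncoding RNA H19 (-5.58 ± 0.40) and S100A7A (-4.86 ± 0.89), a close paralog of S100A7. Of 10 retinoid-response genes, 5 rose, including RARRES1 (4.39 ± 0.31), and 2 fell (the same numbers adjusted over the list alone). The set test gave adjusted p = 0.00116, and adjusted p = 0.330 with an estimated correlation. Of the core genes, the cornified-envelope crosslinking enzyme gene TGM1 fell (-2.02 ± 0.19, adjusted p = 0.000403), while the spinous keratins KRT1 (-1.37 ± 0.63) and KRT10 (-0.98 ± 0.48) and the basal keratins KRT5 (-0.24 ± 0.20) and KRT14 (0.37 ± 0.22) did not pass. The 35 cornified-envelope genes were not called as a list (median -0.05). Late cornified envelope genes were called as a list, higher on CC (adjusted p = 0.0168, and adjusted p = 0.763 with an estimated correlation). Their median was 3.44, or 3.35 with the group without counts at the floor of 3 counts. Of the 15 members, 0 were called by edgeR (0 adjusted over the list alone, 6 higher at an unadjusted p under 0.05), 0 by limma-voom and 4 by DESeq2. That list did not pass without ACD graft 2 (adjusted p = 0.0553) or CC graft 3 (median -0.89, adjusted p = 0.400), and 3 members rose without CC graft 2. Of 24 lipid-barrier genes, 3 fell (1 adjusted over the list alone; median -0.77), DEGS2 (-1.96 ± 0.38), SDR9C7 (-1.44 ± 0.42) and ACER1 (-1.57 ± 0.46), and DESeq2 called 9. This list had adjusted p = 0.00708, and adjusted p = 0.763 with an estimated correlation. It did not pass without ACD graft 1 (adjusted p = 0.0537). In edgeR 1, 1 and 1 members fell without ACD grafts 1, 2 and 3, and 0 and 0 without CC grafts 2 and 3 (2 and 6 at an unadjusted p under 0.05). Only 1 gene of the keratin list rose without ACD graft 2 or 3 or CC graft 2 or 3, and 3 retinoid-response genes rose without CC graft 3.

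Of 13 mitochondrially encoded mRNAs, 6 rose on CC at day 3 (12 adjusted over the list alone; median 0.70). Their list had adjusted p = 2.09e-06, and adjusted p = 0.414 with an estimated correlation. Without CC graft 2, 1 of them rose. In all, 3362 of 18632 genes changed between the scaffolds at day 3, 1665 higher and 1697 lower on CC (edgeR), or 1595 higher and 1324 lower when scaled by library size alone and 1851 and 1599 with RLE scaling. The count was 1744 and 1722 without ACD graft 2 or 3, 1154 and 718 without CC graft 2 or 3, and 5949 in a fit to these 2 groups alone. Of the 31 named genes called, 28, 27 and 27 kept their call without ACD day 3 grafts 1, 2 and 3 and 25 and 21 without CC day 3 grafts 2 and 3.

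At day 7, proliferation genes were lower on CC than on ACD, and interferon-response genes were again higher. Of 27 proliferation genes, 21 fell and 0 rose, with a median log2 fold change of -1.92, among them the mitotic genes KIF20A (-2.87 ± 0.57), AURKA (-1.80 ± 0.36) and CDK1 (-2.32 ± 0.50). Adjusted over the list alone, 25 fell and 1 rose. The proliferation marker MKI67 measured 30.3 ± 15.8 CPM (SD, n = 2) in CC and 151 ± 65.4 CPM (SD, n = 3) in ACD (-2.32 ± 0.53, adjusted p = 0.0133). The list passed at adjusted p = 1.56e-10, and had adjusted p = 0.627 with an estimated correlation. Without CC graft 4, the deepest library, 0 members were called by edgeR, with 20 lower at an unadjusted p under 0.05 in that fit and a median of -1.58. Interferon-response genes rose in 15 of 25 cases (19 adjusted over the list alone), including BST2 (3.10 ± 0.35), IFI27 (2.39 ± 0.28) and OAS1 (1.16 ± 0.15). This list had adjusted p = 1.44e-09, and adjusted p = 0.520 with an estimated correlation. That count was 7 without CC graft 4. NRF2 targets fell in 5 of 14 cases (6 adjusted over the list alone), including NQO1 (-2.48 ± 0.21) and the glutathione synthesis genes GCLM (-1.42 ± 0.21) and GCLC (-1.64 ± 0.25). Camera gave adjusted p = 0.000606, and adjusted p = 0.520 with an estimated correlation. The amino acid synthesis and endoplasmic reticulum stress list, lower on CC at day 3, stood higher on CC at day 7. Its mean log2 CPM was 5.48 and 5.58 in CC day 7 and 4.96 to 5.12 in ACD day 7. Mitochondrial counts took a larger share in these ACD libraries than in the CC ones, and of 12 nuclear-retained transcripts, a list added after the data had been seen, 10 fell (median -1.53).

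The core keratinocyte genes other than MKI67 did not pass between the scaffolds at day 7, while part of the early differentiation list rose. KRT1 (0.21 ± 0.60), KRT10 (0.34 ± 0.47), LORICRIN (0.77 ± 0.73), FLG (-0.29 ± 0.81) and TGM1 (-0.04 ± 0.18) did not pass, nor did KRT5 (-0.52 ± 0.20), KRT14 (-0.42 ± 0.22) and IVL (0.73 ± 0.28). Early differentiation genes rose in 4 of 14 cases (the same number adjusted over the list alone), including CALML5 (2.05 ± 0.42) and KRTDAP (1.29 ± 0.28). As a list, these genes had adjusted p = 0.0368, and adjusted p = 0.678 with an estimated correlation. The lipid-barrier list, lower on CC at day 3, had a mean log2 CPM of 7.18 and 7.30 in CC day 7. It was 5.75, 6.89 and 7.01 in ACD day 7 grafts 4, 5 and 6. Basal keratinocyte genes fell in 4 of 13 cases (the same number adjusted over the list alone), including the epidermal master regulator TP63 (-1.06 ± 0.14) and the Notch ligand DLL1 (-1.97 ± 0.22). The set test gave adjusted p = 0.0283, and adjusted p = 0.678 with an estimated correlation. Without CC graft 4, 0 early differentiation genes rose in edgeR (4 at an unadjusted p under 0.05) and 2 basal genes fell. Neither list passed without ACD graft 4 (adjusted p = 0.241 and 0.184) or without CC graft 4 (adjusted p = 0.0821 and 0.0863). Without ACD graft 4, 4 basal genes rose and 4 fell, with a median of -0.07 against -0.41 on all libraries and -0.18 without CC graft 4. The largest increases were those of the complement gene C3 (ENSG00000125730.18, chromosome 19, 6677704 to 6730562; 4.83 ± 0.61, adjusted p = 0.00124), the collagen gene COL22A1 (3.82 ± 0.61), CLEC2B (3.45 ± 0.44), NELL2 (3.39 ± 0.47), PCDHGA12 (3.28 ± 0.32), which shares exons with its cluster, and UPK3BL2 (5.04 ± 0.81), which has a near-identical copy. The largest decreases were those of GOLGA8A (-5.17 ± 0.42) and GOLGA8B (-5.26 ± 0.49), paralogs that may share reads, the calpain gene CAPN3 (-4.82 ± 0.99), PILRB (-4.60 ± 0.56), the ligand gene WNT3 (ENSG00000108379.11, chromosome 17, 46762506 to 46833154; -4.58 ± 0.34, adjusted p = 0.000144) and IGFBP3 (-4.01 ± 0.48).

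At day 7, 4291 genes changed, 2244 higher and 2047 lower on CC (edgeR), or 1345 higher and 2228 lower when scaled by library size alone. The count was 966 in a fit to these 2 groups alone, 1459 and 2449 without CC graft 4 or 5, and 5686 without ACD graft 4. At both days 620 genes were higher and 451 lower on CC, where independent lists would give 200 and 186, and 150 changed in opposite directions against 387. The contrasts share no library. The number changed the same way, 1071, was 500 and 304 without CC day 3 graft 2 or 3, 427 without CC day 7 graft 4, 635 and 607 without ACD day 3 graft 2 or 3, and 373 with each pair of groups fitted alone. Of the 27 named genes called, 27, 27 and 27 kept their call without ACD day 7 grafts 4, 5 and 6 and 20 and 25 without CC day 7 grafts 4 and 5.

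**Figure D2:**
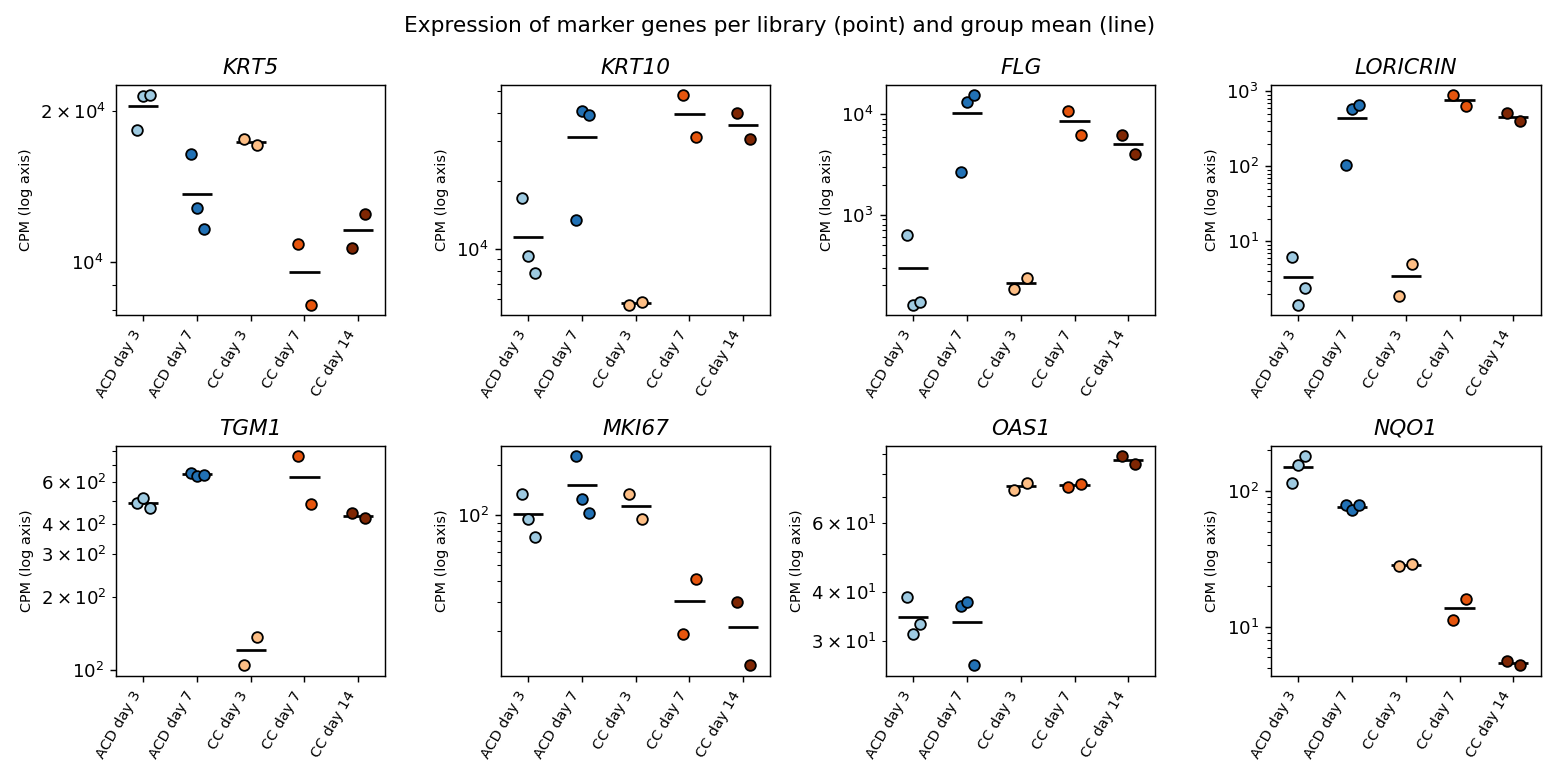
CPM of 8 genes on a log axis, 1 point per library and a line at each group mean, for the 5 groups. KRT10, FLG and LORICRIN are higher at day 7 than at day 3 on both scaffolds, TGM1 and NQO1 are lower in CC than in ACD at day 3, and OAS1 is higher in CC at both days.

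On ACD, cornified-layer and lipid-barrier genes rose from day 3 to day 7 and basement membrane genes fell. Of 35 cornified-envelope and granular genes, 28 rose and 1 fell (31 and 2 adjusted over the list alone), with a median of 2.98, including LORICRIN (7.05 ± 0.88, adjusted p = 0.00161), TCHH (2.85 ± 0.30) and the protease inhibitor SPINK5 (1.68 ± 0.22). The list passed at adjusted p = 8.42e-16, and had adjusted p = 0.423 with an estimated correlation. FLG, the filaggrin precursor, went from 299 ± 288 CPM (SD, n = 3) to 10370 ± 6794 CPM (SD, n = 3), a log2 fold change of 5.12 ± 0.86 (adjusted p = 0.00403). All 15 tested late cornified envelope genes rose (all also adjusted over the list alone; median 7.71). This list had adjusted p = 4.83e-09, and adjusted p = 0.423 with an estimated correlation. These are paralogs in 1 cluster and may share reads. Of 24 lipid-barrier genes, 19 rose and 1 fell (21 and 1 adjusted over the list alone), including the lipoxygenase gene ALOX12B (2.63 ± 0.49) and PNPLA1 (2.49 ± 0.47). Camera gave adjusted p = 1.07e-07, and adjusted p = 0.472 with an estimated correlation. The basal keratin KRT5 fell (-0.59 ± 0.18), and KRT1 (1.97 ± 0.56) and KRT10 (1.46 ± 0.43) rose. Basement membrane genes fell in 10 of 19 cases (12 adjusted over the list alone), including NID1 (-0.69 ± 0.10) and COL17A1 (-0.78 ± 0.12). As a list, these genes had adjusted p = 0.000257, and adjusted p = 0.439 with an estimated correlation. Proliferation genes were not called as a list (median 0.22, camera direction down, adjusted p = 0.995). Lipid-barrier genes rose in 10, 10, 12 and 12 cases without day 3 graft 2, day 3 graft 3, day 7 graft 5 and day 7 graft 6. Basement membrane genes fell in 4 cases without day 3 graft 1, 2 or 3 or day 7 graft 5 or 6.

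All 13 mitochondrially encoded mRNAs also rose on ACD (all also adjusted over the list alone; median 1.39), including MT-ND1 (1.58 ± 0.12). The set test gave adjusted p = 2.34e-24, and adjusted p = 0.289 with an estimated correlation. Of 12 nuclear-retained transcripts, the list added later, 11 rose (median 1.13). The cytokine gene IL37 (8.79 ± 1.39), ELMOD1 (8.52 ± 1.23), KPRP (8.28 ± 1.63) and LCE6A (8.43 ± 1.5) had among the largest increases. The proteases MMP1 (-3.02 ± 0.35) and MMP3 (-3.34 ± 0.86), TIMP1 (-2.78 ± 0.44), IGFBP6 (-2.73 ± 0.74) and SERPINE2 (-2.62 ± 0.52) fell. In all, 5791 genes changed, 2754 higher and 3037 lower at day 7 (edgeR), or 2288 higher and 3598 lower when scaled by library size alone and 3148 and 2518 with RLE scaling. Without ACD day 7 graft 4, which stood apart, the count was 8915. It was 2895 and 3095 without day 7 graft 5 or 6, 3116 and 3451 without day 3 graft 2 or 3, and 3000 in a fit to these groups alone. Of the 24 named genes called, 23, 18 and 19 kept their call without ACD day 3 grafts 1, 2 and 3 and 24, 18 and 21 without ACD day 7 grafts 4, 5 and 6.

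On CC, lipid-barrier, cornified-layer and spinous genes rose from day 3 to day 7, and proliferation genes fell. Of 24 lipid-barrier genes, 22 rose and 0 fell (the same numbers adjusted over the list alone; median 2.13), including the ceramide pathway genes DEGS2 (3.95 ± 0.43), CERS4 (2.02 ± 0.27) and ACER1 (4.15 ± 0.54). This list had adjusted p = 6.2e-18, and adjusted p = 0.305 with an estimated correlation. Cornified-envelope and granular genes rose in 28 of 35 cases (29 adjusted over the list alone), including TGM1 (2.38 ± 0.21), LORICRIN (7.78 ± 1.10) and SPINK5 (3.24 ± 0.29). Camera gave adjusted p = 1.37e-17, and adjusted p = 0.330 with an estimated correlation. Early differentiation genes of the spinous layer rose in 11 of 14 cases and fell in 1 (the same numbers adjusted over the list alone; median 2.69), including SERPINB12 (4.26 ± 0.29) and CALML3 (4.54 ± 0.47). The spinous list passed at adjusted p = 9.61e-11, and had adjusted p = 0.305 with an estimated correlation. KRT1 (3.55 ± 0.73, adjusted p = 0.00720), KRT10 (2.78 ± 0.55) and FLG (5.35 ± 1.06) rose, and KRT5 (-0.86 ± 0.22), KRT14 (-1.17 ± 0.24) and MKI67 (-1.91 ± 0.54) fell. Of 20 transcription factors of differentiation, 14 rose and 2 fell (the same numbers adjusted over the list alone), including CEBPB (1.19 ± 0.17), EHF (1.24 ± 0.20) and OVOL1 (2.30 ± 0.36). As a list, these genes had adjusted p = 1.38e-05, and adjusted p = 0.367 with an estimated correlation. Proliferation genes fell in 10 of 27 cases and rose in 1 (14 and 1 adjusted over the list alone), the latter being the transcription factor gene E2F1 (1.5 ± 0.36). The set test gave adjusted p = 2.32e-05, and adjusted p = 0.471 with an estimated correlation. Hypoxia and glycolysis genes rose in 8 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone), including EGLN3 (3.56 ± 0.29) and PFKFB3 (1.27 ± 0.12). This list had adjusted p = 3.13e-06, and adjusted p = 0.305 with an estimated correlation. Without day 3 graft 2, 12 cornified-envelope genes, 7 spinous genes and 5 transcription factors rose, and 8 transcription factors rose without day 7 graft 4. In edgeR, 0, 0 and 4 proliferation genes fell without day 3 graft 2, day 7 graft 4 and day 3 graft 3 (8, 7 and 18 at an unadjusted p under 0.05).

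The largest increases on CC were those of HRNR (9.57 ± 1.57, adjusted p = 0.00301), ARG1 (8.84 ± 1.38), IL37 (8.67 ± 1.62), SERPINA12 (7.96 ± 1.56) and C1orf68 (7.84 ± 1.54), and the largest decreases those of the growth factor genes BMP6 (-4.16 ± 0.83) and FGF1 (-3.93 ± 0.89), CCNA1 (-4.02 ± 0.88), TFPI2 (-3.97 ± 1.24), IL7R (-3.75 ± 1.10) and KRT19 (-3.71 ± 1.03). In all, 5288 genes changed, 2836 higher and 2452 lower at day 7 (edgeR), or 2029 higher and 3930 lower when scaled by library size alone. The count was 1564 and 2563 without day 3 graft 2 or 3, and 3127 and 2892 without day 7 graft 4 or 5. Of the 32 named genes called, 19 and 25 kept their call without CC day 3 grafts 2 and 3 and 28 and 25 without CC day 7 grafts 4 and 5. The day 7 against day 3 changes on ACD and on CC share no library, but share the spread estimates of 1 fit. Called higher on both scaffolds were 1336 genes and lower on both 992, against 419 and 400 for independent lists, and 179 changed in opposite directions against 825.

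**Figure D3:**
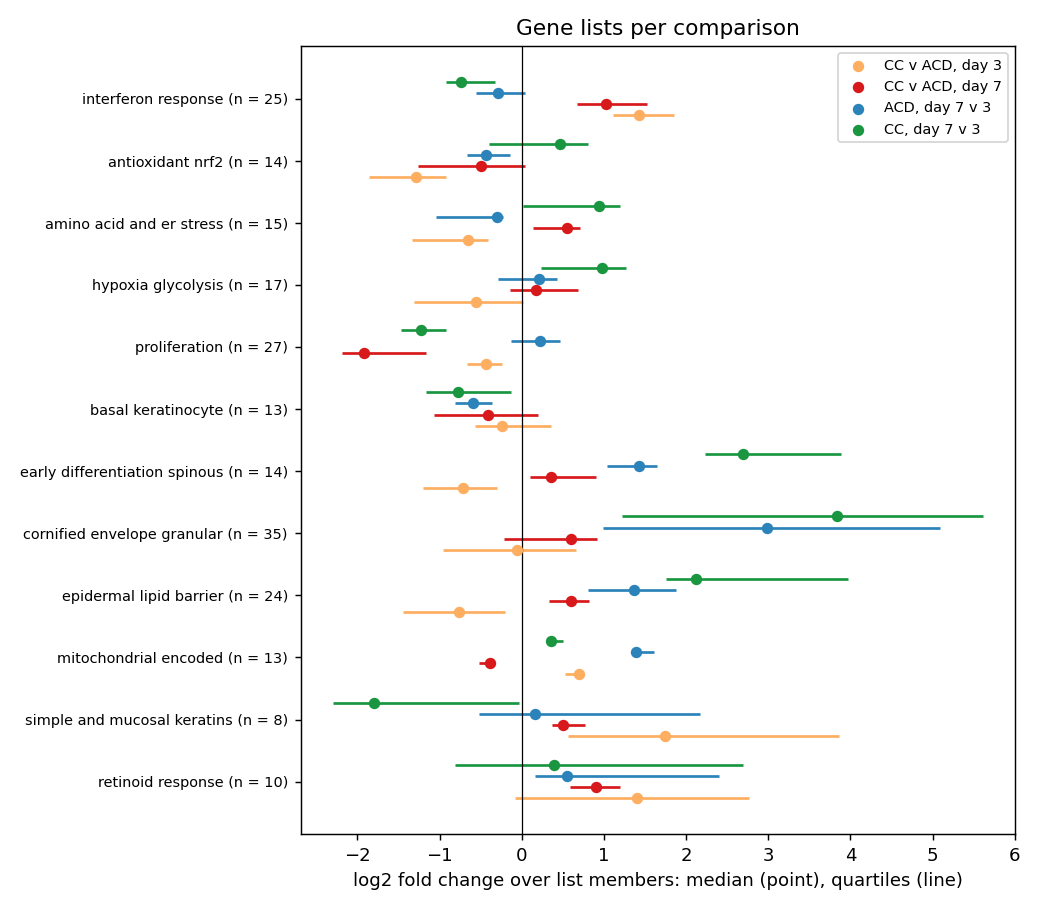
Median (point) and quartiles (line) of the log2 fold change over the tested members of 12 gene lists, on the horizontal axis, in 4 comparisons told apart by colour. Interferon-response genes lie above 0 for CC against ACD at both days, and cornified-envelope genes lie above 0 for day 7 against day 3 on both scaffolds.

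Between day 7 and day 14 on CC, 495 genes passed, and none of the 10 core genes was among them in edgeR. The growth factor genes BTC (5.32 ± 0.83, adjusted p = 0.0194) and EPGN (2.03 ± 0.33), the alarmin gene IL33 (2.15 ± 0.32), MFAP5 (1.77 ± 0.18) and TUBA1A (1.66 ± 0.35) rose. SERPINA1 (-3.48 ± 0.72), TMPRSS11A (-2.84 ± 0.53), the Wnt receptor and ligand genes FZD10 (-2.34 ± 0.34) and WNT10A (-2.19 ± 0.36), CSGALNACT1 (-2.25 ± 0.43) and CD68 (-2.21 ± 0.45) fell. Amino acid synthesis and endoplasmic reticulum stress genes fell in 3 of 15 cases (8 adjusted over the list alone), PHGDH (-1.85 ± 0.19), PSAT1 (-1.32 ± 0.27) and ASNS (-1.65 ± 0.35). Camera gave adjusted p = 3.2e-08, and adjusted p = 0.0725 with an estimated correlation. KRT10 (-0.16 ± 0.51), FLG (-0.74 ± 0.88) and LORICRIN (-0.74 ± 0.82) did not pass. The fibroblast marker list was higher at day 14, with 3 of 17 genes called (3 adjusted over the list alone), MFAP5, FBN1 (2.54 ± 0.41) and COL5A2 (0.91 ± 0.20). The fibroblast list had adjusted p = 0.000403, and adjusted p = 0.307 with an estimated correlation. The melanocyte list was also higher (adjusted p = 0.0128, and adjusted p = 0.180 with an estimated correlation), with TYRP1 (3.77 ± 0.83) called of 6 genes (3 adjusted over the list alone). The endothelial list was lower (adjusted p = 0.0133, and adjusted p = 0.307 with an estimated correlation). Of its 4 genes, edgeR called 0 (0 adjusted over the list alone, 2 lower at an unadjusted p under 0.05), DESeq2 0 and limma-voom 1. Without day 7 graft 4, day 7 graft 5, day 14 graft 7 and day 14 graft 9, edgeR called 1, 1, 2 and 1 fibroblast and 0, 1, 0 and 0 melanocyte genes (1, 4, 3 and 4 of the latter at an unadjusted p under 0.05). The endothelial list had adjusted p = 0.129, 0.0771 and 0.0574 without day 7 graft 5, day 14 graft 7 and day 14 graft 9. The calls split into 170 higher and 325 lower at day 14, or 192 and 127 when scaled by library size alone. The count was 129 and 9 without day 14 graft 7 or 9, and 100 and 54 without day 7 graft 4 or 5. Of the amino acid and stress genes, 0 fell without day 14 graft 9 (8 at an unadjusted p under 0.05) and 1 without day 14 graft 7 or day 7 graft 4 or 5. Of the 17 named genes called, 7 and 1 kept their call without CC day 14 grafts 7 and 9 and 6 and 3 without CC day 7 grafts 4 and 5.

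Against day 3, cornified-envelope genes were higher on CC at day 14 and proliferation genes lower. Cornified-envelope genes were higher in 20 of 35 cases (26 adjusted over the list alone), including TGM1 (1.85 ± 0.20) and TCHH (2.58 ± 0.35). As a list, these genes had adjusted p = 5.23e-18, and adjusted p = 0.350 with an estimated correlation. Proliferation genes were lower in 22 of 27 cases (25 adjusted over the list alone), including PLK1 (-2.31 ± 0.50) and MKI67 (-2.42 ± 0.55). The set test gave adjusted p = 1.29e-14, and adjusted p = 0.399 with an estimated correlation. SERPINA12 (9.0 ± 1.59), ARG1 (7.99 ± 1.33) and the transglutaminase gene TGM3 (7.05 ± 1.51) were among the largest increases, and the prostaglandin transporter gene SLCO2A1 (-6.37 ± 0.79), BMP6 (-5.58 ± 0.91) and the fatty acid desaturase gene FADS2 (-4.12 ± 0.44) among the largest decreases. Of 12 nuclear-retained transcripts, 6 were higher (median 0.59), 3 when scaled by library size alone, and in edgeR 0, 0, 0 and 0 without day 3 graft 2, day 3 graft 3, day 14 graft 7 and day 14 graft 9 (6, 7, 5 and 6 at an unadjusted p under 0.05). The melanocyte list was higher (adjusted p = 0.0230, and adjusted p = 0.350 with an estimated correlation), with 2 of 6 genes called (3 adjusted over the list alone), PMEL (1.13 ± 0.23) and TYRP1 (2.64 ± 0.77). In edgeR 0, 0, 0 and 0 of them were called with these libraries left out in the same order (2, 2, 3 and 4 at an unadjusted p under 0.05), and the list had adjusted p = 0.0586 after thinning. The fibroblast list did not pass (adjusted p = 0.241), but had adjusted p = 0.000555 without day 14 graft 7. In all, 2633 genes changed, 1325 higher and 1308 lower (edgeR), or 1114 higher and 1462 lower when scaled by library size alone and 1326 and 1395 with RLE scaling. The count was 299 and 288 without day 3 graft 2 or 3, 706 and 729 without day 14 graft 7 or 9, and 5258 in a fit to these groups alone. Without day 3 graft 2, day 3 graft 3, day 14 graft 7 and day 14 graft 9, 3, 4, 9 and 11 cornified-envelope genes were higher in edgeR. In the same order, 0, 0, 7 and 0 proliferation genes were lower (22, 25, 25 and 22 at an unadjusted p under 0.05). Of the 12 named genes called, 8 and 8 kept their call without CC day 14 grafts 7 and 9 and 5 and 5 without CC day 3 grafts 2 and 3.

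**Figure D4:**
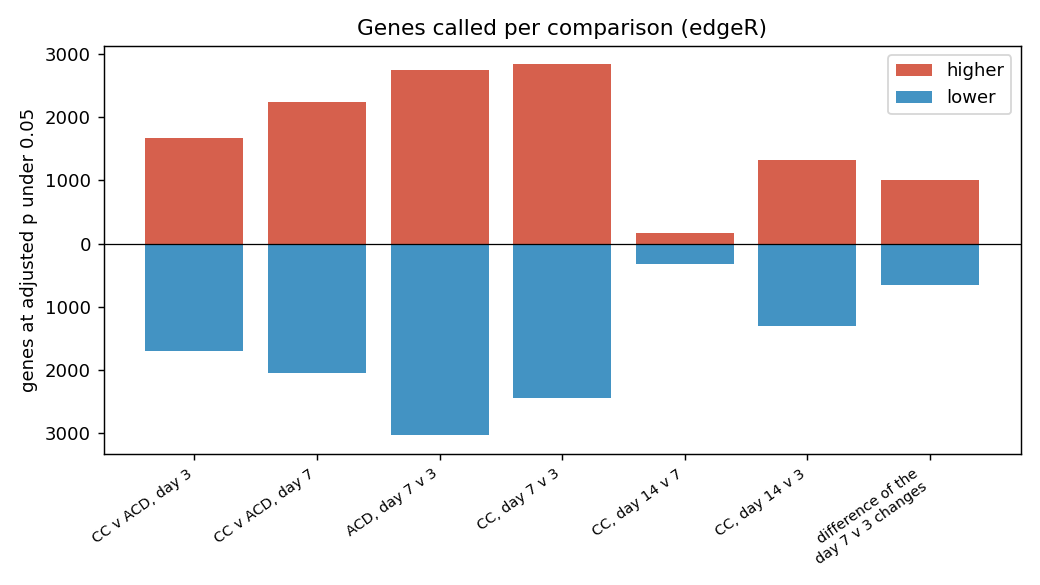
Number of genes at adjusted p under 0.05 (edgeR), higher above and lower below the line, in 7 contrasts. The CC day 14 against day 7 contrast has the fewest, 495.

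The change from day 3 to day 7 was compared between the scaffolds as a difference of changes, CC minus ACD. Amino acid synthesis and endoplasmic reticulum stress genes were more positive on CC in 9 of 15 cases (10 adjusted over the list alone), with PHGDH at 2.26 ± 0.24, PSAT1 at 2.25 ± 0.35 and ASNS at 2.75 ± 0.45. This list passed at adjusted p = 4.51e-11 and also at adjusted p = 0.0457 with an estimated correlation. TGM1 rose more on CC (1.98 ± 0.26, adjusted p = 0.00473), while KRT1 (1.58 ± 0.85), KRT10 (1.32 ± 0.67), LORICRIN (0.73 ± 1.09) and FLG (0.23 ± 1.14) did not pass. The melanosomal and lysosomal protein gene GPNMB (4.74 ± 0.32) measured 41.9 ± 3.53 CPM in CC day 3 and 983 ± 227 CPM in CC day 7 (SD, n = 2 each), against 942 ± 25.8 and 827 ± 177 CPM in ACD (SD, n = 3 each). UPK3BL2 (6.49 ± 1.12), the aldehyde dehydrogenase gene ALDH3A1 (5.05 ± 1.10), the peptidase gene DPP4 (4.11 ± 0.47), ZBTB16 (3.92 ± 0.55) and the lipid droplet gene PLIN2 (3.77 ± 0.67) were also more positive on CC. PILRB (-4.11 ± 0.70), GOLGA8A (-3.98 ± 0.51), RARRES1 (-3.70 ± 0.42), the amino acid transporter gene SLC6A14 (-3.44 ± 0.58), ID3 (-3.06 ± 0.32) and ENC1 (-2.85 ± 0.56) were more negative. Of 12 nuclear-retained transcripts, the list added later, 6 were more negative on CC (median -1.13), at an unadjusted camera p = 5.24e-10, and unadjusted p = 0.0167 with an estimated correlation. Mitochondrially encoded mRNAs were more negative in 9 of 13 cases (12 adjusted over the list alone; median -1.05). Their list had adjusted p = 2.97e-11, and adjusted p = 0.481 with an estimated correlation. Without CC day 3 graft 2, day 3 graft 3 and day 7 graft 5, 3, 3 and 2 nuclear-retained transcripts and 1, 2 and 2 mitochondrial mRNAs were called. The latter were 5, 4 and 5 without ACD day 3 graft 2, day 3 graft 3 and day 7 graft 5. In all, the change differed for 1667 genes, more positive on CC for 1012 and more negative for 655 (edgeR), or 490 and 753 when scaled by library size alone. The count was between 249 without CC day 3 graft 2 and 3307 without ACD day 7 graft 4. It was 356 without CC day 3 graft 3, 400 without CC day 7 graft 5, 815 without ACD day 7 graft 5, and 966, 698 and 899 without ACD day 3 grafts 1, 2 and 3. Of the amino acid and stress genes, 2, 3, 5 and 4 passed without CC day 3 graft 2, day 3 graft 3, day 7 graft 4 and day 7 graft 5. Of the 16 named genes called, 16, 15 and 15 kept their call without ACD day 3 grafts 1, 2 and 3, 16, 15 and 16 without ACD day 7 grafts 4, 5 and 6, 11 and 11 without CC day 3 grafts 2 and 3 and 16 and 11 without CC day 7 grafts 4 and 5.

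CC day 3 and ACD day 7, at 5 days from the start of submerged culture and 7 days from seeding per the protocols, lay apart in differentiation. Whether the ACD cultures were also submerged at first is not given in the sources used here, so the times at the air-liquid interface cannot be set side by side. LORICRIN (-7.01 ± 1.05, adjusted p = 0.00130), FLG (-5.63 ± 1.05), KRT1 (-3.34 ± 0.69), KRT10 (-2.44 ± 0.52) and TGM1 (-2.42 ± 0.20) were lower in CC day 3 and KRT14 (0.74 ± 0.22) higher. Interferon-response genes were higher in 24 of 25 cases and lower in 1 (the same numbers adjusted over the list alone), including IFI27 (2.56 ± 0.28). This list had adjusted p = 2.4e-14, and adjusted p = 0.319 with an estimated correlation. Genes of wound migration and proteolysis were higher in 12 of 18 cases and lower in 1 (13 and 1 adjusted over the list alone), including MMP1 (2.68 ± 0.37) and the urokinase gene PLAU (3.05 ± 0.46). Camera gave adjusted p = 1.18e-05, and adjusted p = 0.445 with an estimated correlation. SMOC1 (5.55 ± 0.64), C3 (5.52 ± 0.63) and MYH15 (6.14 ± 0.69) were among the largest increases, and ARG1 (-8.96 ± 1.37), APOB (-8.63 ± 1.16) and TGM3 (-8.54 ± 1.55) among the largest decreases. Of 12 nuclear-retained transcripts, 12 were lower in CC day 3 (median -1.38). In all, 6818 genes differed, 3451 higher and 3367 lower in CC day 3 (edgeR), or 4047 higher and 2771 lower when scaled by library size alone and 3250 and 3572 with RLE scaling. A fit to these groups alone gave 3634. The count was 3267 and 3498 without CC graft 2 or 3. Of the 17 named genes called, 17, 16 and 16 kept their call without ACD day 7 grafts 4, 5 and 6 and 13 and 15 without CC day 3 grafts 2 and 3.

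Markers of other cell types were tested as lists where enough members were measured. The leukocyte and adipocyte lists had fewer than 3 tested members and were not tested. Summed counts of the fibroblast collagens COL1A2 and COL3A1 were 7 and 2 on ACD and 64 and 20 on CC. Of 9 endothelial markers, 4 were tested. The untested KDR, CLDN5, CDH5, ESAM and TEK had summed counts of 0, 0, 19, 4 and 3 on ACD and 8, 2, 17, 20 and 45 on CC. The untested melanocyte markers SOX10 and KIT had 3 and 7 on ACD and 5 and 25 on CC. A call of these lists therefore does not show that such cells were present. The fibroblast list was not called between the scaffolds at day 3 (adjusted p = 0.778) or day 7 (adjusted p = 0.435). COL1A1, the core gene of that list, measured 42.5 ± 3.99 CPM in ACD day 7 (SD, n = 3) and 57.0 ± 27.4 CPM in CC day 7 (SD, n = 2) and did not pass (0.42 ± 0.28). The melanocyte list was lower on CC at day 7, with 2 of 6 genes called (4 adjusted over the list alone), including TYRP1 (-4.25 ± 0.81), which measured 2.85 ± 1.48 CPM in ACD day 7 (SD, n = 3) and 0.171 ± 0.193 CPM in CC day 7 (SD, n = 2). As a list, these genes had adjusted p = 0.0283, and adjusted p = 0.520 with an estimated correlation. The melanocyte list did not pass without ACD graft 4 (adjusted p = 0.0669), without CC graft 4 (adjusted p = 0.0523) or after thinning (adjusted p = 0.0554), and 1 gene was called without CC graft 4 or 5. It was higher on ACD at day 7 than at day 3, with 3 of 6 genes called (3 adjusted over the list alone), PMEL (1.13 ± 0.19), MITF (1.11 ± 0.27) and TYRP1 (2.31 ± 0.63). The set test gave adjusted p = 0.0268, and adjusted p = 0.423 with an estimated correlation, or adjusted p = 0.198 without ACD day 7 graft 4, and 1 gene was called without day 3 graft 3. It was lower in CC day 3 than in ACD day 7, with 3 genes called (3 adjusted over the list alone), including PMEL (-1.45 ± 0.22) and TYRP1 (-3.12 ± 0.75). That test gave adjusted p = 0.0251, and adjusted p = 0.319 with an estimated correlation, or adjusted p = 0.115 without ACD graft 4 and 0.0552 after thinning, and 1 gene was called without CC graft 2 or 3. The endothelial list was higher on CC at day 7 than at day 3 (adjusted p = 0.0334, and adjusted p = 0.390 with an estimated correlation), with 2 of 4 genes called (2 adjusted over the list alone). They were PECAM1, which had no count in CC day 3, and the von Willebrand factor gene VWF, which went from 1.09 ± 0.165 to 53.4 ± 12.4 CPM (SD, n = 2 each; 5.61 ± 0.91) and measured 16.1 ± 1.04 CPM in CC day 14 (SD, n = 2). The list had adjusted p = 0.0551, 0.0653 and 0.102 without CC day 3 graft 3, without CC day 7 graft 5 and after thinning. It was not called between the scaffolds at day 7 on all libraries (adjusted p = 0.142), but was higher on CC without ACD graft 5 (adjusted p = 0.0307). On ACD between the days, the fibroblast list had adjusted p = 0.0846, and was lower at day 7 without day 3 graft 3 (adjusted p = 0.0444). The smooth muscle list was not called on all libraries in any contrast, with adjusted p = 0.117 or higher. Without CC day 14 graft 7 it was higher at day 14 than at day 7 (adjusted p = 0.0328; median 1.11), with 0 of 4 members called by edgeR and 1 higher at an unadjusted p under 0.05. In contrasts not given above, nuclear-retained transcripts had medians of -0.33 for CC against ACD at day 3, 0.38 for day 7 against day 3 on CC and 0.30 for day 14 against day 7. Their unadjusted camera p was 0.0118, 0.197 and 0.00585, and p = 0.261, 0.547 and 0.218 with an estimated correlation, and the first was 0.0596 without ACD graft 3.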

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

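The tests of single libraries, depth, library batch, dilution, differentiation stage and time from seeding were chosen after the results had been seen. The list of nuclear-retained transcripts was also added after the data had been seen, though before its own values were, and the count of other splits was set before its result was seen. The day 7 against day 3 change differed between CC and ACD, by a test of the difference itself, for 1667 genes. The CC minus ACD differences in log2 change were 6.49 for UPK3BL2, 5.05 for ALDH3A1, 4.74 for GPNMB, 4.11 for DPP4, 3.92 for ZBTB16, 3.77 for PLIN2 and 1.98 for TGM1. They were -4.11 for PILRB, -3.98 for GOLGA8A, -3.70 for RARRES1, -3.44 for SLC6A14, -3.06 for ID3 and -2.85 for ENC1. Median differences over the members of the lists called in this contrast were 1.34 for lipid barrier, 1.29 for early differentiation, 1.20 for amino acid synthesis and endoplasmic reticulum stress, 0.89 for NRF2 targets, 0.76 for hypoxia and glycolysis, 0.69 for activation keratins and alarmins, 0.58 for transcription factors of differentiation, 0.26 for cornified envelope, -0.53 for YAP targets, -1.05 for mitochondrially encoded and -1.59 for proliferation genes. With an estimated correlation, the amino acid synthesis and endoplasmic reticulum stress list alone kept its call.

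Interferon-response genes were higher on CC at both days. Thinning every library to the smallest total left their median at 1.43 at day 3 and 1.05 at day 7. On all counts it was 1.43 and 1.02. Thinning keeps each gene's expected share of the counts. It therefore speaks only to counting error at lower depth and cannot decide on another cause that goes with depth. With any 1 library left out, at least 13 of 25 members were called at day 3 and the day 7 median was 0.79 or higher, which argues against a single library. The number called at day 7 went from 15 to 7 without CC graft 4, where 1 CC library is left and calls over all genes went from 4291 to 1459, so this loss does not tell a single library from lower power. Total counts of the scaffolds did not overlap, the lowest CC total being 1.35 times the highest ACD total, and RN7SL1, RN7SL2 and RN7SL3 were higher and RN7SK lower in every CC than in every ACD library, so a batch or difference in library preparation and the scaffold cannot be told apart. The scaffold, the medium and the donors stay open as untested biological explanations.

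Mitochondrially encoded mRNAs rose on ACD between day 3 and day 7. The rise was smaller on CC, by a median of -1.05 on the log2 scale, although CC differentiated over the same days. The list also rose on CC (median 0.35, 1 of 13 called, camera adjusted p = 0.0446, not called with an estimated correlation). On CC it already stood higher at day 3, with a mean log2 CPM of 10.68 and 10.93 against 9.78 to 10.32 on ACD. At day 7 it was 11.14 and 11.23 on CC and 11.45 to 11.73 on ACD. Part of the difference thus lay in the start, so the smaller rise cannot decide on differentiation. On ACD, all 13 members stayed called whichever library was left out. A list chosen for nuclear retention, among them the noncoding RNAs MALAT1 and NEAT1, also rose on ACD with a median of 1.13 and 11 of 12 members called. The noncoding KCNQ1OT1 was not called (0.76 ± 0.55). The members other than these noncoding RNAs are protein-coding genes, whose counts per gene do not tell nuclear from exported mRNA. Loss of cytoplasmic RNA from damaged cells may contribute, but this list cannot decide it. A biological change in the mitochondrially encoded mRNAs was not tested and stays open.

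Proliferation genes were lower on CC at day 7. Dilution by cornified-layer transcripts would lower basal genes as much, but their median was -0.41 against -1.92, or -0.07 against -1.41 without ACD graft 4 and -0.18 against -1.58 without CC graft 4, which argues against it. Without CC graft 4, 0 members were called by edgeR (20 at an unadjusted p under 0.05), but calls over all genes fell too, from 4291 to 1459 with 1 CC library left, so the loss does not tell a single library from lower power. The median was -1.41 or further from 0 with any 1 library left out, and the mean log2 CPM of the list in the remaining CC graft 5 was 3.42 against 4.21 to 5.26 in ACD day 7, which argues against a single library. The extremes were CC graft 4 at 2.6 and ACD graft 4 at 5.26, with ACD grafts 5 and 6 at 4.37 and 4.21. Leaving out 1 library at a time does not remove both extremes, so the size of the change may rest in part on them. A later time from seeding on CC, if the cells were on it during submerged culture, cannot be told apart from the scaffold, as a submerged phase on ACD is not given in the sources used here and the list was not called between days 3 and 7 on ACD (median 0.22).

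For ACD day 7 against day 3, the real split of the 6 libraries gave 5791 genes and the highest of the other 9 splits gave 0 at the same threshold in edgeR, with at most 4427 at an unadjusted p under 0.05. The real split was the 1 split of 10 with as many genes, and so few splits cannot give a share under 0.05.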

How the results depend on the processing

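The replicate-block fit, the scalings, tools, filters, thresholds and left-out libraries were planned, and thinning and the principal components of protein-coding genes were chosen after the results were seen. Values in this order refer to CC against ACD at day 3 and day 7, day 7 against day 3 on ACD and on CC, day 14 against day 7 and day 14 against day 3 on CC, the difference of the day changes, and CC day 3 against ACD day 7. Counts of genes under settings or contrasts not given here stayed within 1.5 times the main counts, and no gene called in the main setting was called in the opposite direction under any setting. At an adjusted p under 0.01 the counts were 1211, 1661, 2084, 2236, 14, 585, 270 and 3645, and with glmTreat at a fold of 1.5 they were 628, 912, 1077, 1516, 9, 469, 228 and 2718, both stricter by construction. The genes changed the same way at both days numbered 297 and 145. Fits to the compared groups alone gave 5949 and 966 for the scaffolds at day 3 and day 7 (373 shared), 3000 for ACD days, 1263 and 5258 for day 14 against day 7 and day 3, and 3634 for CC day 3 against ACD day 7. For day 14 against day 7, DESeq2 gave 1732, limma-voom 1061 and library size alone 319, and DESeq2 gave 4166 for day 14 against day 3 and 2874 for the difference of the day changes. The cause was not tested. The SD of log2 ratios was 0.588 and 0.720 in the pairs with ACD day 7 graft 4, against 0.234 to 0.328 in the other pairs within groups. ACD day 7 thus had a wider spread than the pooled fit assumes. Fits to the compared groups alone gave fewer genes than the main fit in every contrast with ACD day 7 and more in the others. Standard errors and p-values of contrasts with ACD day 7 may therefore be too small in the main fit. Library size alone shifted the median log2 fold change of all genes to -0.15 on ACD and -0.24 on CC for day 7 against day 3, and to 0.14 for day 14 against day 7, so changes near these sizes depend on the scaling. After thinning, the counts were 3258, 3867, 5512, 4958, 436, 2392, 1465 and 6340.

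With each library left out in turn, which removes samples, the counts ranged from 718 to 2606, 1459 to 5686, 2895 to 8915, 1564 to 3127, 9 to 129, 288 to 729, 249 to 3307 and 3267 to 8983, and the genes shared by both days from 304 to 1237. The lists called for the scaffolds at day 7 ranged from 6 to 15. The late cornified envelope median at day 3 between the scaffolds ranged from -0.89 to 5.08, and the activation keratin and alarmin median for day 14 against day 7 from -0.73 to -0.0154, and the camera direction turned without CC day 3 graft 3 in the first and without CC day 7 graft 4 in the second. Genes that were not called and changed sign were, for the scaffolds at day 7, KRT1 (-0.23 to 0.49), KRT10 (-0.0312 to 0.58), FLG (-0.78 to 0.0650), TGM1 (-0.42 to 0.22) and COL1A1 (-0.20 to 0.82). For day 14 against day 7 it was KRT10 (-0.45 to 0.16), which stood at 0.00107 with library size alone, and for the difference of the day changes FLG (-0.94 to 0.59) and LORICRIN (-0.0957 to 1.62). With an estimated correlation camera called 1 list for the difference of the day changes and 0 in each other contrast, where 4, 1, 2, 4, 5, 2, 2 and 4 lists had an unadjusted p under 0.05, taking the contrasts in order.

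Whether grafts with the same number share a donor or batch between scaffolds is not given in the sources used here. Correlations of deviations from the group means were taken between libraries with the same number. They were 0.0876 and 0.000371 at day 3 and -0.0529 and -0.0794 at day 7. Each ACD library had correlations of the same size and opposite sign with the CC libraries of its day, whose deviations mirror each other. These correlations therefore cannot show or exclude pairing. With the graft number as a replicate block, edgeR called 512 genes at day 3, 139 at day 7, 46 the same way at both, and 0 for the difference of the day changes, where 3170 had an unadjusted p under 0.05 and no other tool was run with the block. That fit held the day 3 and day 7 libraries alone and spent coefficients on graft numbers. It left far fewer residual degrees of freedom than the 7 of the main fit, so its lower counts do not tell pairing from lower power. Of the single-gene results followed across settings, 53 were unchanged under the block, 43 lost their call and 2 changed sign. In fits to the compared groups alone, 182 were unchanged, 20 lost their call and 1 gained a call. FLG changed sign under the block at day 7 (0.45) and for the difference of the day changes (-0.21), called in neither fit. Depth limits low genes most on ACD, where totals were lower.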

Other observations

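Both lists tested here were added after ZBTB16, ALDH3A1 and UGT1A7 had been seen to be lower, and before the values of the lists themselves were seen. Their p-values are unadjusted, from 3 lists added in this way. On CC at day 3, glucocorticoid target genes other than ZBTB16 were lower, with a median log2 fold change of -0.68 and 5 of 12 called, among them, chosen after their values were seen, TSC22D3 (-2.29 ± 0.31) and FKBP5 (-1.34 ± 0.17), at an unadjusted camera p of 5.33e-05, or 0.0136 with an estimated correlation. At day 7 the median was -0.06 (camera p of 0.486), although TSC22D3 (-0.99 ± 0.29) and FKBP5 (-0.84 ± 0.17) stayed lower. A lower glucocorticoid response on CC may therefore accompany the low ZBTB16 at day 3. The day 7 against day 3 change of ZBTB16 was more positive on CC by 3.92 on the log2 scale. That did not make up its day 3 difference, so ZBTB16 stayed lower on CC at day 7, where the list median was -0.06. The list median thus does not go with the lower ZBTB16 at day 7. It cannot decide on the response there, as TSC22D3, FKBP5 and GLUL (-0.58 ± 0.18) were still called lower, while MT1X stood higher without passing (1.275 ± 0.425). The medium of the ACD cultures is not given in the labels, so medium and scaffold cannot be separated.

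A list of aryl hydrocarbon receptor targets, from which ALDH3A1 and the UGT1A genes had been left out, had 3 tested members. At day 3 its median on CC against ACD was -0.86, with 2 called lower, named after their values were seen, CYP1B1 (-3.46 ± 0.72) and TIPARP (-0.86 ± 0.09), at an unadjusted camera p of 0.00378. With an estimated correlation p was 0.111, and at day 7 the median was -0.18 with CYP1B1 still lower (-3.42 ± 0.75). The remaining member, CYP1A1, was not called at day 3 (-0.62 ± 0.79) or day 7 (-0.18 ± 0.79). TIPARP was not called at day 7 (-0.03 ± 0.09). Lower receptor activity on CC may be 1 explanation for the low ALDH3A1, but so small a list limits the test.

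The noncoding RNAs RN7SL1, RN7SL2, RN7SL3 and RN7SK were chosen after their values were seen. RN7SL1 measured 31.8 ± 0.843 CPM in CC day 3 (SD, n = 2) and 1.60 ± 0.181 CPM in ACD day 3 (SD, n = 3), and 36.2 ± 30.1 CPM in CC day 7 (SD, n = 2) and 0.832 ± 0.763 CPM in ACD day 7 (SD, n = 3). The lowest CC and highest ACD libraries stood at 14.9 and 1.74 CPM for RN7SL1, 42.2 and 4.15 CPM for RN7SL2 and 4.71 and 0.224 CPM for RN7SL3, which are near-identical copies and may share reads. RN7SK went the other way, with the lowest ACD library at 3.67 CPM and the highest CC library at 3.21 CPM. None of these RNAs has a poly-A tail of its own. Over 78 readthrough genes, the median log2 fold change of CC against ACD was -0.07 at day 3 and 0.01 at day 7.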
